A study of Mus musculus with 10 samples.

How the data were processed

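PolyA RNA from interscapular brown adipose tissue of mice was sequenced in 10 strand-specific libraries (dUTP method), 5 from PnocCre and 5 from Wildtype animals. Every sample was taken 1 h after an injection of clozapine-N-oxide (CNO), the ligand of designer receptors, per the labels' protocols. The labels name 1 factor, the genotype, and give no batch, litter or sex. Each library carries its own number, but no label states outright that the libraries are separate animals, so the p-values measure the spread between these samples. Replicate numbers were given in accession order within a group and pair no samples.

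Per the submitters' processing notes, the tools were HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 (no version stated), and the genome build was GRCm39. The annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap or have near-identical copies are reported as uncertain. The deposited table holds 26863 genes. Its values per library are a signal that the authors made by dividing the read count of each gene by 1 size factor per library. Whole reads could be recovered from it: 100% of the values of every library were whole multiples of 1 step at a tolerance of 0.01 reads, which gave 21304238 to 29171787 reads per library. Size factors ran from 0.858 to 1.21. The deposited group means equalled the means of the 5 columns to within 4.00e-04. The authors' log2 fold changes (PnocCre over Wildtype) and the deposited p-values and adjusted p-values are in the same table, where an adjusted p of 1 stands for 10130 genes that DESeq2 leaves without one. The gene length, another deposited column per the file headers, was used in no test.

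The design fixed before the data were examined takes limma-trend as the main test for values of this kind. It was run with robust moderation on log2(value + 1) for the 15301 genes with a mean of at least 10 normalised counts, with Benjamini-Hochberg adjustment, 2-sided, and a threshold of 0.05 on the adjusted p. Log2 fold changes are on this scale, which understates the change of genes that are low in every library. For genes near 0 in only some libraries it can give larger values than DESeq2, as for Ckmt2 (4.71 against 2.78). Gene lists fixed before the data were examined (34, with a sex-linked list kept as a check) were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were measured, which left 31. Camera with an estimated correlation, fry and an exact permutation test of the mean log2 value of the members were run beside it. Aldoa has 2 rows in the table and counts as 2 members of its list. The mesothelial and epithelial list and the neutrophil list had fewer than 5 measured members and were not tested.

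On the recovered reads, edgeR's quasi-likelihood test, DESeq2 and limma-voom were run as alternatives. Others were rescaling by TMM factors, other filters and pseudocounts, library weights, 1 surrogate variable, genes on X and Y left out, and each library left out in turn. Chosen after the data were seen were DESeq2 with libraries left out, the mean of the skeletal muscle markers as a covariate, voom with library quality weights, the exact list test, and the count of genes whose groups do not overlap. Several of these tools had been tried on the data before the final scripts were written, and the count of each is given. A sex covariate could not be fitted, since every library had Y-linked transcripts. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and sva 3.50.0.

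Genes named in the text follow a rule fixed before the data were examined. It takes Pnoc, 18 genes given whatever their p, the 6 smallest p per direction with a mean of at least 50 normalised counts (used because fewer than 5 genes passed the threshold), and the 4 members with the smallest p of each called list, or 2 of the others. The rule gave 125 genes, and the text names a part of them. Pnoc itself was not analysed here, and some single-gene results are not reported here. The metabolic lists weighed in the closing section are the called lower lists without the heat shock list, which was left out after its values were seen because it is not metabolic, and the median of the members is -0.34 with or without it. A test of their mean level over the splits with the lists held fixed, set beforehand, was dropped because the lists had been picked on the same grouping, and the test of muscle dilution over all members was replaced by 1 test per part of the lists. The bound of that test was first stricter, which left dilution open for the 6 lists outside the respiratory chain, and was loosened after the interval was seen to an interval that excludes 0. The closing section draws no conclusion on dilution from either bound. The adipocyte genes used in the closing section were listed before their test.

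The tests were run on simulated counts of the 15301 genes with the libraries' own depths and dispersions, 5 against 5. With the thermogenic list shifted, 100 genes changed 2-fold and 100 changed 4-fold, limma recovered 76 and 95, with 12 false among 190 calls. For edgeR the numbers were 75 and 95, with 11 false of 189. DESeq2 recovered 85 and 97, with 46 false of 236 calls, so its false calls went past the limit of 10% first set for all 3 tools, which was then kept for limma and edgeR only. Camera found a list shifted by -0.6 on the log2 scale, and called 0 of the 24 lists that share no gene with it. The genes were simulated independently of each other, while the estimated correlation within the real skeletal muscle list was 0.91. The simulation therefore does not test camera's false calls where the members of a list move together.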

Results

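The data describe the transcriptome of interscapular brown adipose tissue, the heat-producing fat depot of the mouse, 1 h after CNO was given to PnocCre and Wildtype animals. PNOC neurons of the medial preoptic area, a hypothalamic region that sets body temperature, were the cells activated, by the series' description. The designer receptor, and whether Wildtype animals carried it, are not given in the sources used here. There were 5 libraries per genotype, with 21304238 to 29171787 recovered reads each. Mitochondrially encoded transcripts took 16.1% to 20.7% of the reads of a library, and the most abundant gene (mt-Co1 or Scd1) took 5.18% to 8.93%. All 10 libraries carried Y-linked transcripts, with Eif2s3y at 1573 to 1914 normalised counts and Xist at no more than 7.21. No pair of libraries of a group was a duplicate: chi-square per degree of freedom was at least 19.1, and correlations of log2 values within a group ran from 0.916 to 0.984.

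The comparison of PnocCre with Wildtype asks how the brown fat of the animals described as having these neurons activated differs from that of controls. Brown-fat and lipid genes had lower levels in PnocCre and stromal and muscle genes had higher ones, as groups with camera at a preset correlation, while 0 genes passed the main test. With an estimated correlation, fry in 1 direction or the exact test of list means, 0 lists passed. In the exact test even lists at its smallest possible p had an adjusted p of 0.123. Ucp1, the uncoupling protein that makes heat in brown fat (chromosome 8, 84016981 to 84025081), had 64072 ± 4732 normalised counts in PnocCre and 98965 ± 11808 in Wildtype (SD, n = 5 each). Elovl3, a fatty acid elongase of brown fat (chromosome 19, 46120336 to 46124133), had 2250 ± 551 against 5195 ± 1530. Mef2c, a transcription factor of muscle and endothelium (chromosome 13, 83652153 to 83815199), had 610 ± 110 against 277 ± 63.4. limma called 0 of 15301 genes at an adjusted p under 0.05, and its smallest adjusted p was 0.101. At an unadjusted p under 0.05 there were 2603 genes, 1368 higher and 1235 lower, where 765 would come by chance.

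The tools disagreed on this count. edgeR's quasi-likelihood test called 0 of 15070 genes (2569 at an unadjusted p under 0.05) and limma-voom called 0. DESeq2 called 575, of which 368 were higher and 207 lower, and these are the same 575 genes as in the authors' deposited table. Weighting libraries by their quality gave 53 calls with limma and 53 with voom, and 1 surrogate variable gave 12. Without PnocCre replicate 2 DESeq2 called 292 genes, without Wildtype replicate 2 it called 216, without Wildtype replicate 4 it called 273, and without Wildtype replicate 5 it called 241. Without PnocCre replicate 3, limma called 1 gene, Trp53inp1, a p53-induced gene named here after its value was seen (log2 fold change 1.27, SE 0.14, adjusted p 0.0427). The values of the 2 groups did not overlap for 673 genes, 274 higher and 399 lower, or 4.40% of those tested, where chance gives 0.794% (121 genes). With 1 library left out the number ran from 761 (without PnocCre replicate 2) to 1219 (without Wildtype replicate 1), where the chance share of 9 libraries is 1.59%. It was 789 without Wildtype replicate 4, 1010 without PnocCre replicate 3, 1040 without PnocCre replicate 4 and 1055 without PnocCre replicate 5.

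**Figure D1:**
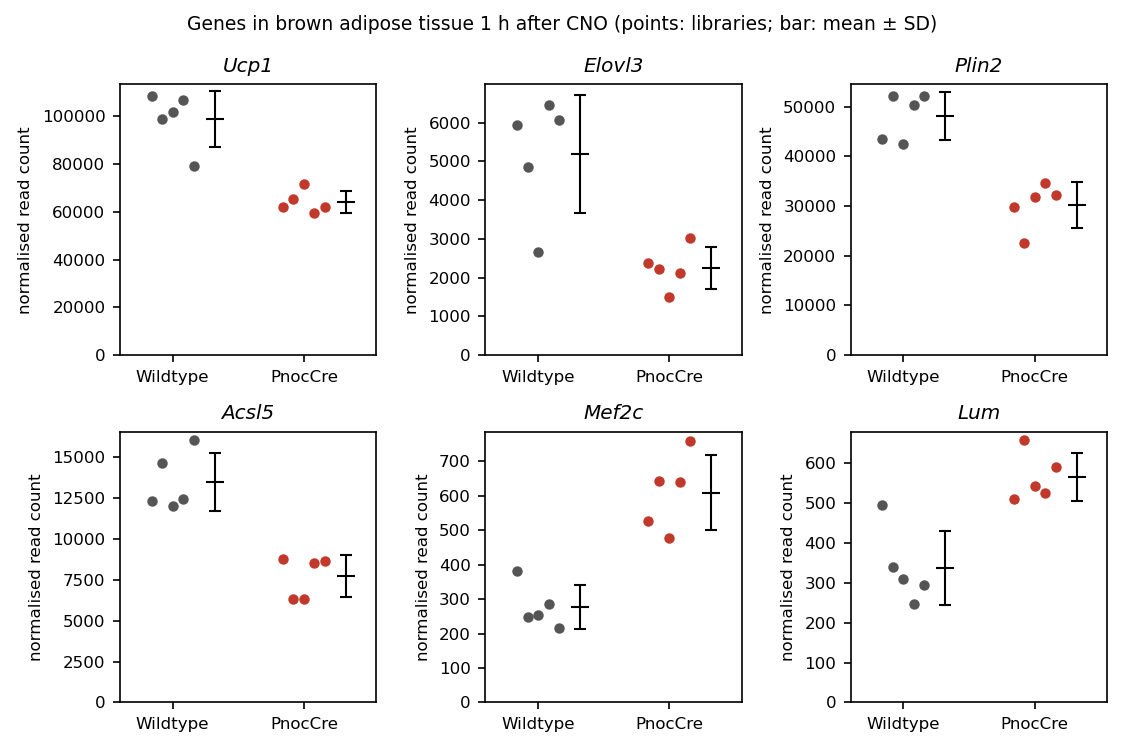
Normalised read counts of 6 genes (vertical axes, linear from 0) in the 5 Wildtype and 5 PnocCre libraries (points), with the mean and SD of each group (bars). For Ucp1, Plin2, Acsl5, Mef2c and Lum the groups do not overlap, while for Elovl3 1 Wildtype library lies among the PnocCre libraries.

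Among the genes with the smallest p-values, 0 passed limma's threshold. On the lower side were Acsl5, an acyl-CoA synthetase (7730 ± 1268 against 13509 ± 1771, log2 fold change -0.81, SE 0.14), Fabp5, a fatty acid carrier (-0.61), Tmem254 (-1.05), Mkks (-0.76), Rpia, an enzyme of the pentose phosphate pathway (-0.51), and Nipsnap1 (-0.58). On the higher side were Mef2c (1.14, SE 0.17), the sodium channel Scn7a (0.67), Clmp (1.40), Nrep (0.96), the matrix proteoglycan Podn (0.86) and Pacsin3 (0.64). Their adjusted p with limma was 0.101 for each of the 12. The authors' deposited table was ranked only over named protein-coding genes that are reported here and have a mean of at least 50 normalised counts. Among these the smallest p was that of Mef2c (log2 fold change 1.13, adjusted p 2.31e-05). The amino acid transporter Slc38a3 (3.09, adjusted p 2.31e-05) and the matrix protein Cilp (3.21, adjusted p 3.99e-05) followed. Ucp1 stood at -0.63 there (adjusted p 7.43e-05). Slc38a3 and Cilp were picked from that table after their values were seen.

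The thermogenic program, the genes of brown-fat identity and heat production, fell as a list with camera (median log2 fold change -0.35, 24 of 29 measured members lower, adjusted p 3.74e-05), but not with an estimated correlation (adjusted p = 0.358). In the same PnocCre libraries the markers of skeletal muscle (median 5.33), fibroblasts (0.67) and white adipocytes (1.08) were higher as lists. Beside Ucp1 (log2 fold change -0.62, SE 0.12, limma adjusted p 0.116) and Elovl3 (-1.18, SE 0.25, adjusted p 0.116), it held Letmd1, a mitochondrial protein needed for thermogenesis (-0.72), and Esrra, a nuclear receptor of mitochondrial genes (-0.39). With p adjusted over the list alone 6 members passed, all lower, against 0 over all genes, and DESeq2 called 5. The other genes of the program that were fixed by name did not pass with limma or DESeq2. Ppargc1a, the coactivator induced by cold, had 879 ± 209 in PnocCre and 900 ± 210 in Wildtype (limma adjusted p 0.920). Dio2, which activates thyroid hormone, had 613 ± 288 and 924 ± 573 (adjusted p 0.683), and log2 fold changes were -0.22 for Cidea, -0.38 for Adrb3, -0.35 for Prdm16 and -0.34 for Cpt1b. Fgf21 had 6.91 ± 2.63 and 13.5 ± 6.62 counts.

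Lists of lipid metabolism fell with camera at the preset correlation, in the same PnocCre libraries whose skeletal muscle markers were higher as a group (median log2 fold change 5.33). Fatty acid and triglyceride synthesis had a median of -0.52 with all 24 members lower (adjusted p 5.38e-08, or adjusted p = 0.358 with an estimated correlation). Its members with the smallest p were Acsl5, the citrate carrier Slc25a1 (-0.70), Agpat2 (-0.53) and Gpd1 (-0.75), while Fasn, the fatty acid synthase, stood at -0.67 with an SE of 0.32. Cholesterol synthesis had a median of -0.59 with 19 of 21 lower (adjusted p 8.89e-07, or adjusted p = 0.362 with an estimated correlation), among them Cyp51 (-0.70), Nsdhl (-0.63), Mvd (-0.77) and Hmgcs1 (-0.40). Lipolysis and lipid droplet genes had a median of -0.35 with 18 of 21 lower (adjusted p 8.90e-05, or adjusted p = 0.410 with an estimated correlation). Plin2, a coat protein of lipid droplets, had 30229 ± 4666 counts in PnocCre and 48158 ± 4784 in Wildtype, and Plin5 had 4869 ± 823 and 6926 ± 371. The lipases Pnpla2 (-0.38) and Lipe (-0.35) had limma adjusted p-values of 0.306 and 0.316. Fatty acid uptake and oxidation had a median of -0.36 with 25 of 30 lower (adjusted p 1.64e-06, or adjusted p = 0.358 with an estimated correlation), with the smallest p for Cpt2 (-0.53), Slc25a20 (-0.47), Ech1 (-0.42) and Decr1 (-0.36). Adjusted over the list alone, 4, 2, 2 and 13 members of these 4 lists passed, against 0 over all genes with limma, and DESeq2 called 4, 2, 2 and 5 of them.

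Glucose uptake and glycolysis fell likewise in these libraries (median -0.44, 24 of 30 lower, camera adjusted p 8.89e-07, or adjusted p = 0.358 with an estimated correlation). Mpc1, a subunit of the mitochondrial pyruvate carrier, had 3745 ± 305 against 5126 ± 355, and the glycolytic enzymes Pfkl, Eno1 and Gpi1 stood at -0.83, -0.61 and -0.56. Adjusted over the list alone 13 members passed on the lower side and 1 on the higher side, against 0 over all genes with limma. Pdk4, which shuts off pyruvate oxidation, had 41455 ± 15475 and 55881 ± 12953. Respiratory chain lists had smaller shifts of the median, a difference between lists that was not tested. The nuclear-encoded list had a median of -0.15 with 43 of 51 lower (adjusted p 1.45e-05, or adjusted p = 0.508 with an estimated correlation), and the mitochondrially encoded list a median of -0.22 with 11 of 13 lower (adjusted p 0.0379, or adjusted p = 0.512 with an estimated correlation). The mitochondrially encoded list did not pass without PnocCre replicate 1, 3 or 5 or without Wildtype replicate 1, 2 or 5 (medians from -0.23 to -0.16). The nuclear-encoded median was -0.24 without PnocCre replicate 1, -0.09 without PnocCre replicate 4, -0.10 without PnocCre replicate 5 and -0.079 without Wildtype replicate 1, and passed each time. With the muscle marker mean as a covariate neither list passed with camera. The nuclear-encoded median was then 0.057 (adjusted p 0.792) and the mitochondrially encoded one -0.13 (adjusted p 0.227). Adjusted over the list alone 0 members of either passed with limma, as over all genes, and DESeq2 called 2 and 0. Heat shock genes, of which 0 passed with limma over the list alone or over all genes, fell as a list with camera too (median -0.34, 18 of 20 lower, adjusted p 2.04e-04, or adjusted p = 0.410 with an estimated correlation), with Hspb8 at -0.49 and Fkbp4 at -0.31, while Cryab, a small heat shock protein of muscle, stood at 0.66. Hspa1a, which has a near-identical copy, had 134 ± 152 and 112 ± 77.3.

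**Figure D2:**
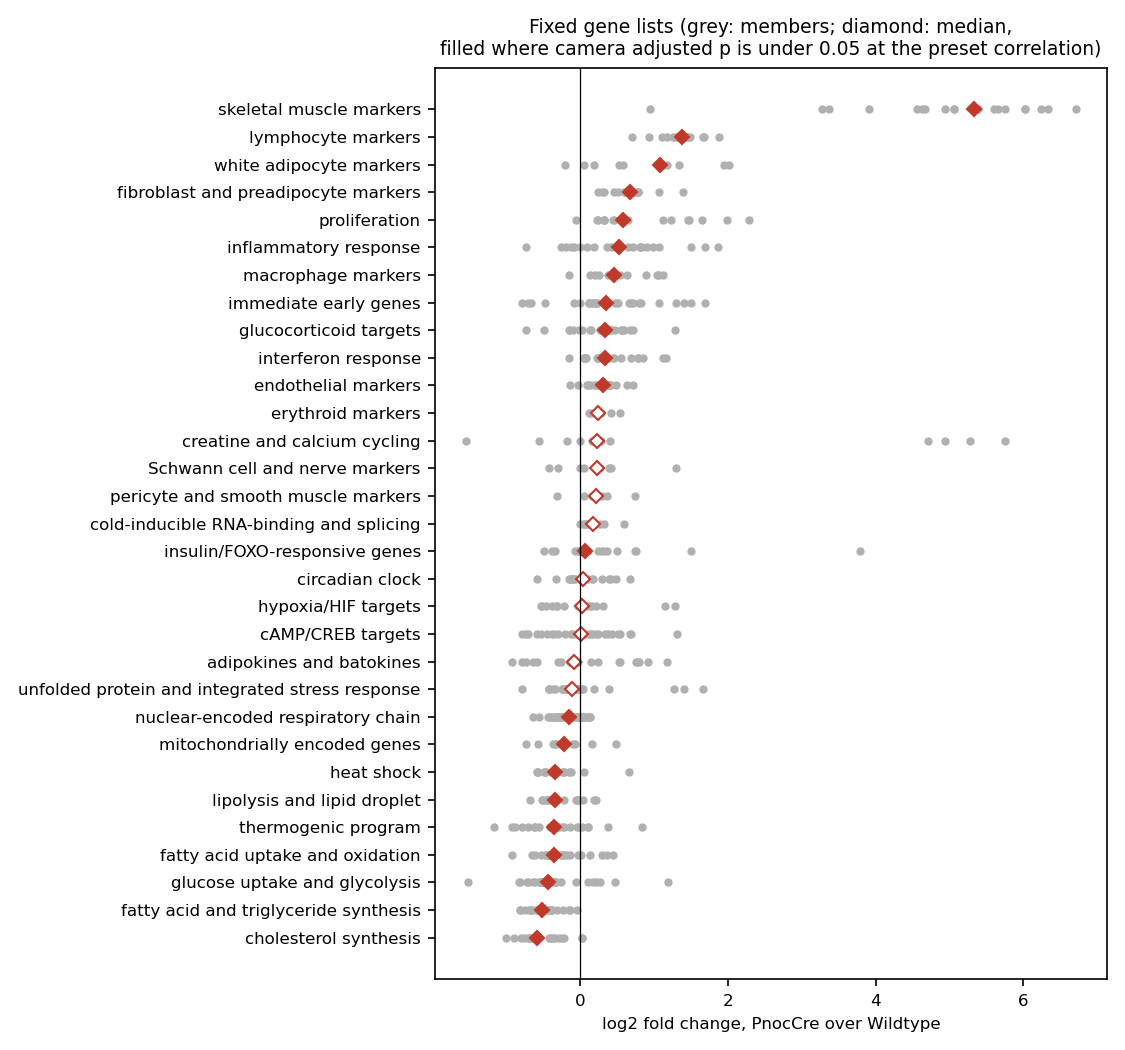
Log2 fold change of PnocCre over Wildtype (horizontal axis) of the measured members of the 31 tested lists (grey points, 1 row per list) and their median (diamonds, filled where camera at the preset correlation gave an adjusted p under 0.05). The 9 called lists on the lower side have medians from -0.59 to -0.15, and the skeletal muscle markers have a median of 5.33.

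On the higher side, skeletal muscle markers stood apart. All 21 were higher in PnocCre, with a median log2 fold change of 5.33 (camera adjusted p 6.78e-12, or adjusted p = 0.358 with an estimated correlation). Tnnt1, a slow troponin, had 591 ± 522 against 30.6 ± 39.5, and Mylpf, a fast myosin light chain, had 2461 ± 1949 against 277 ± 356, while Myl1 differed least among those named (0.94). Of these markers 18 passed adjusted over the list alone, against 0 over all genes with limma, and DESeq2 called 3. The mean log2 level of the markers was 10.5 ± 1.94 in PnocCre and 5.50 ± 3.74 in Wildtype (SD, n = 5 each, exact permutation p 0.0397, adjusted 0.154). It ranged from 7.64 to 12.7 in PnocCre, and 2 Wildtype libraries, replicates 3 and 4, lay within that range at 9.50 and 9.48. In the same libraries the creatine and calcium cycling gene Ckmt2 had 544 ± 465 and 79.0 ± 106, and the muscle ubiquitin ligase Trim63 had 105 ± 95.4 and 11.5 ± 15.4.

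Stromal and immune cell markers rose as lists with camera. Fibroblast and preadipocyte markers had a median of 0.67 with 16 of 16 higher (adjusted p 1.07e-07, or adjusted p = 0.358 with an estimated correlation). Lum had 566 ± 60.2 and 337 ± 94.0, Dpt 1325 ± 503 and 618 ± 141, and Dcn and Col1a2 stood at 0.64 and 0.76. Macrophage markers had a median of 0.46 with 12 of 13 higher (adjusted p 9.41e-06, or adjusted p = 0.358 with an estimated correlation), among them Mrc1 (0.64), Fcgr1 (1.06) and Csf1r (0.54). Endothelial markers had a median of 0.31 with 14 of 16 higher (adjusted p 0.00674, or adjusted p = 0.575 with an estimated correlation), with Plvap at 0.71. Lymphocyte markers had a median of 1.38 with 18 of 18 higher (adjusted p 0.00109, or adjusted p = 0.542 with an estimated correlation), but their mean log2 level was 9.04 in PnocCre replicate 2 and 3.06 to 4.46 in the other PnocCre libraries, against 3.44 ± 0.12 in Wildtype. Without PnocCre replicate 2 the lymphocyte median was 0.31 (adjusted p 0.0461), and without PnocCre replicate 1 the endothelial median was 0.18 (adjusted p 0.103). White adipocyte markers had a median of 1.08 with 10 of 11 higher (adjusted p 2.04e-04, or adjusted p = 0.358 with an estimated correlation), among them Retn, a hormone of fat cells (1246 ± 512 and 522 ± 161), Sncg (1.34) and Agt (1.95). Skeletal muscle markers were higher in the same PnocCre libraries (median 5.33). With their mean as a covariate the white adipocyte list did not pass with camera (0.75, adjusted p 0.095), while the fibroblast, macrophage, endothelial and lymphocyte lists did. Adjusted over the list alone, 8 fibroblast, 8 macrophage, 0 endothelial, 0 lymphocyte and 6 white adipocyte markers passed, against 0 over all genes with limma, and DESeq2 called 6, 3, 0, 1 and 3.

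**Figure D3:**
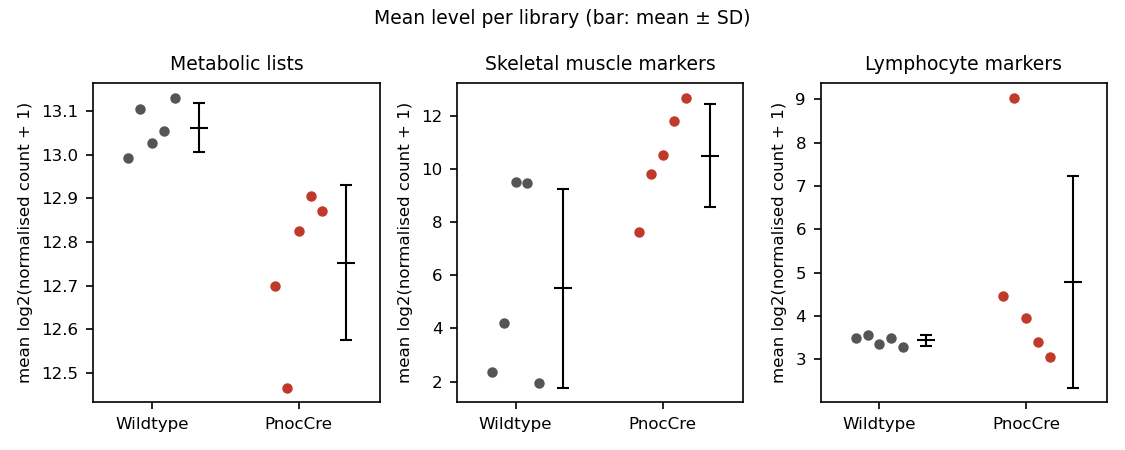
Mean log2(normalised count + 1) per library (vertical axes, each with its own range, not starting at 0) of the 212 members of the metabolic lists that were lower in PnocCre, of the skeletal muscle markers and of the lymphocyte markers, with the mean and SD of each group (bars, n = 5 each). The metabolic means, of lists taken because they were lower, do not overlap between groups, the muscle markers vary widely within Wildtype, and 1 PnocCre library stands apart in lymphocyte markers.

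Proliferation genes rose with camera (median 0.58, 16 of 17 higher, adjusted p 5.25e-07, or adjusted p = 0.358 with an estimated correlation), from low levels. Top2a, a DNA topoisomerase of dividing cells, had 44.4 ± 29.4 and 9.07 ± 3.05 counts, Mki67 55.6 ± 31.1 and 17.7 ± 3.78, and Ccnb1 26.2 ± 4.81 and 7.93 ± 2.69. Interferon response genes had a median of 0.33 with 22 of 23 higher (adjusted p 8.90e-05, or adjusted p = 0.426 with an estimated correlation), with the smallest p for Ifit3 (1.12) and Oasl2 (0.78). Glucocorticoid targets had a median of 0.33 with 16 of 22 higher (adjusted p 0.00470, or adjusted p = 0.358 with an estimated correlation), with Sult1a1 at 0.71, Ddit4 at 1.29, the clock gene Per1 at 0.67 and Fkbp5, a chaperone of the receptor, at 0.57. Their median was 0.18 without PnocCre replicate 1 (adjusted p 0.0475) and 0.20 without Wildtype replicate 5 (adjusted p 0.0263). Adjusted over the list alone 4, 1 and 2 members of these 3 lists passed, against 0 over all genes with limma. DESeq2 called 4, 1 and 2 of them. The same PnocCre libraries had, as a group, more muscle and fibroblast transcripts than Wildtype (medians 5.33 and 0.67). PnocCre replicate 2, the library rich in lymphocyte markers, had the highest mean log2 level of proliferation genes (6.42, against 5.46 to 5.93 in the other PnocCre libraries) and of interferon response genes (7.52, against 6.63 to 7.28), with Top2a at 87.2 and Mki67 at 108. Without it the medians were 0.42 (camera adjusted p 2.62e-06) and 0.24 (adjusted p 8.56e-04), and without PnocCre replicate 4 the interferon median was 0.50.

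Acute signalling genes varied between libraries of a group. Immediate early genes rose as a list with camera (median 0.34, 23 of 29 higher, adjusted p 0.0279, or adjusted p = 0.617 with an estimated correlation), while 0 members passed with limma over the list alone or over all genes, and DESeq2 called 0. Fos had 782 ± 804 and 215 ± 188, and Nr4a1 1181 ± 703 and 684 ± 317. Inflammatory response genes had a median of 0.53 with 18 of 24 higher (adjusted p 0.0160, or adjusted p = 0.617 with an estimated correlation), with Tnfaip3 at 0.90 and Nfkbia at 0.47. PnocCre replicate 1 stood apart with a mean log2 level of 7.98, against 6.13 to 6.57 in the other PnocCre libraries and 4.65 to 7.23 in Wildtype. The inflammatory list did not pass without PnocCre replicate 1 (median 0.22, adjusted p 0.372), Wildtype replicate 1 (0.37, adjusted p 0.0573) or Wildtype replicate 5 (0.17, adjusted p 0.304). Its median was 0.89 without Wildtype replicate 3 (camera adjusted p 1.95e-04). The immediate early list did not pass without PnocCre replicate 1 (0.21, adjusted p 0.433), PnocCre replicate 4 (0.32, adjusted p 0.101), Wildtype replicate 1 (0.26, adjusted p 0.188) or Wildtype replicate 5 (0.13, adjusted p 0.380), and its median was 0.55 without Wildtype replicate 3. The insulin and FOXO list passed as higher with a median of only 0.06 (14 of 21 higher, adjusted p 0.0454, or adjusted p = 0.426 with an estimated correlation), with Cited2 at 0.75 and Igfbp3 at 0.74, and it holds the muscle gene Trim63. It did not pass without PnocCre replicate 3, 4 or 5 or without Wildtype replicate 1, 2 or 5 (medians from 0.017 to 0.12). It passed without PnocCre replicate 1 (0.17) or 2 (0.12) or Wildtype replicate 3 (0.12) or 4 (0.13). Skeletal muscle markers were higher in the same PnocCre libraries (median 5.33), and with their mean as a covariate the immediate early and the insulin and FOXO medians were -0.056 (adjusted p 0.864) and -0.14 (adjusted p 0.798). With p adjusted over the list alone, 0 inflammatory and 3 insulin and FOXO members passed, against 0 over all genes with limma, and DESeq2 called 0 and 3. Targets of cAMP and CREB, which follow beta-adrenergic signalling, had a median of 0.01 (15 higher, 15 lower, adjusted p 0.853). Within that list Rgs2, a brake on G-protein signalling, had 3582 ± 1519 and 1336 ± 284, and the transcription factor Cebpb had 3554 ± 506 and 6016 ± 1503.

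In all, camera at the preset correlation called 21 of 31 lists, 12 higher and 9 lower. With an estimated correlation it called 0, fry called 0 in 1 direction and 18 in either direction, and the exact permutation test of list means called 0 after adjustment (smallest adjusted p 0.123), with 0.00794 as the smallest unadjusted p that 5 against 5 allows. The proliferation and macrophage lists reached that smallest p and still stood at 0.123 after adjustment, so the 0 of the exact test says little. With the muscle marker mean as a covariate the camera count was 14. The lists that no longer passed were the nuclear-encoded (median 0.057) and mitochondrially encoded (-0.13) respiratory chain, glucocorticoid targets (0.24), inflammatory (0.11), immediate early (-0.056), insulin and FOXO (-0.14), white adipocyte (0.75) and muscle (0.055), and the erythroid list did pass (0.97).

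A Cre driver at the Pnoc locus can carry passenger sequence, so genes around Pnoc were compared with all others. Pnoc lies between Zfp395 and Elp3 on chromosome 14, by the gene order of a RefSeq table of another build. Within 10 Mb, 30 of 153 genes had an unadjusted limma p under 0.05 (19.6%), against 17.0% elsewhere (odds ratio 1.19, 95% interval 0.770 to 1.79, Fisher's exact p 0.387, 2-sided). Within 5 Mb it was 17 of 74 (odds ratio 1.46, 95% interval 0.794 to 2.55). DESeq2 called 3 of the 153.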

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

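Chosen after the result was seen were the tests of the scaling factors, of muscle dilution in each part of the metabolic lists, of metabolic lists chosen anew in each split, of the shared component of the muscle markers and of the splits for limma's calls, while the other tests named here had been set before theirs.

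The lower level of the metabolic lists, whose 212 members had a mean log2 level of 12.8 ± 0.18 in PnocCre and 13.1 ± 0.06 in Wildtype (SD, n = 5 each) and were taken because their lists were lower, was set against 4 explanations, with the genotype as the biological one. When the called lists among 9 metabolic ones (with creatine and calcium cycling, which holds muscle genes) were chosen anew in each split, 24 of 100 splits gave a difference as large (0.31, highest other 1.99). The lists differed between splits: the real grouping called 8 in 1 direction, as some other splits did, while 1 list alone gave 1.96 in another split. Unlike sets are thus compared, so this test cannot decide on chance, which is not excluded. The muscle marker mean as a covariate was chosen after the data were seen. With it the median of all members was -0.38 (-0.34 without). The nuclear-encoded respiratory chain median went from -0.15 to 0.057 and the mitochondrially encoded one from -0.22 to -0.13. For the other 6 lists it went from -0.40 to -0.49, and their mean level difference then had a 95% interval from -0.87 to -0.07. The covariate is a mean of log2 levels, with Acta1 from 3.29 counts in Wildtype replicate 1 to 50000 in PnocCre replicate 5, while dilution would follow the amount of muscle RNA. It also correlated with the group (r = 0.68), so this fit cannot decide on dilution by muscle for any part of the lists. TMM rescaling gave a median of -0.32 over all members but moved the median of all genes only from -0.0062 to 0.020, so it does not test the scaling factors. A lower share of adipocyte RNA stays open too, as does an effect of the genotype, which was not tested apart from these. The 13 adipocyte genes outside the lists had a median of -0.22, although Cfd stood at 0.75 and Adipoq at -0.07. The 95% bootstrap interval of that median, -0.44 to -0.07, came from resampling the genes. It does not measure the spread between libraries.

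Higher skeletal muscle transcripts in PnocCre may come from muscle tissue carried along at dissection. The first component held 96.8% of the variance of the 21 markers over the libraries. Markers that rise together within the tissue itself would give this too, so the share cannot tell the sources apart. Ratios between markers were not fixed: their median SD over the libraries was 1.44 on the log2 scale, against 4.22 for the levels. Whether the tissue itself made these transcripts was not tested. The marker level differed between groups with an exact permutation p of 0.0397 (adjusted 0.154 over the 31 lists), whatever its source.

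The 575 DESeq2 calls are the pattern on which tools differ most. On genes with a mean of at least 10, DESeq2 called 640, and 5 of 100 splits gave as many (highest other 2869), so chance cannot be excluded. The groups did not overlap for 60.7% of the 549 calls among the genes that limma tested. These genes were called for differing between the same groups, so that share cannot argue against a few outlying libraries. With 1 library left out, 36.2% (without Wildtype replicate 2) to 80.2% (without PnocCre replicate 4) of the 575 remained called, with fewer samples. With the muscle covariate DESeq2 called 459 genes, 131 of them (22.8%) among the 575, without PnocCre replicate 2 it called 292, of which 268 (46.6%) were, and with both changes 172, of which 63 (10.96%) were. Muscle and lymphocyte transcripts in some libraries could explain such a loss, but the muscle covariate correlated with the group (r = 0.68), which can itself cost calls. With both changes the median log2 fold change of the 575 went from 1.37 to 0.99 for the higher and from -0.46 to -0.44 for the lower calls, 100% kept their sign and the median SE rose from 0.24 to 0.34, and the parts of smaller folds and of lost precision were not separated.

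Splits of the libraries bear on 3 further counts, and here and above the real grouping is itself 1 of the 100 splits counted. For limma's 2603 genes at an unadjusted p under 0.05, 6 of 100 splits gave as many (highest other 4662), so chance cannot be excluded. Its count of 0 adjusted calls is reached by any split (100 of 100, highest other 1600), which tests nothing. For the 21 lists called by camera 3 of 100 splits gave as many (highest other 21), and for the 673 genes whose groups do not overlap 4 of 100 did (highest other 1359). Both shares lie under 0.05, but narrowly, and the 100 splits are a draw from 126. No allowance was made for the several counts tested in this way, so chance is not excluded for either count. The count of lists also holds only with the preset correlation. The 4 other splits with most DESeq2 calls all put PnocCre replicates 1, 2 and 3 together with Wildtype replicate 1, which points to a structure of the samples that the genotype does not describe.

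Single libraries stood far from the others of their group in 29 of 312 groups of 5 values tested, by the gap to the nearest library as a share of the range. Independent, normally distributed values would give 15.6. Most of the groups were untransformed counts, and list means hold some of the same genes, so an excess over chance is not shown. PnocCre replicate 2 was the library apart for Cd79a (666 normalised counts), Cd37 (905), Ighm (3120), Pik3ip1 (389), Cyc1 (19576) and the mean log2 level of the lymphocyte list (9.04). PnocCre replicate 1 was apart for Hspa1a (404), Scn7a (708), Ier2 (1896), Cited2 (161), Tnfaip3 (275), Cldn5 (6041) and the inflammatory list (7.98). PnocCre replicate 4 was apart for Dio2 (1121) and Prdm16 (1059). PnocCre replicate 3 was apart for Plin5 (6278) and Sncg (1754), and PnocCre replicate 5 for mt-Atp6 (40256). Wildtype replicate 1 was apart for Pacsin3 (399), mt-Atp8 (340.04), Pik3ip1 (125), Ifit3 (93.9), Plvap (314), Robo4 (1359) and the endothelial list (10.8). Wildtype replicate 3 was apart for Ccn1 (1117), Ighm (267), Sncg (613) and the white adipocyte list (8.501). The genes mt-Atp6 and mt-Atp8 overlap, so their split of reads is uncertain.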

How the results depend on the processing

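The muscle covariate, the DESeq2 variants, the exact list test, voom with quality weights and the DESeq2 calls near Pnoc were chosen after the data were seen. Limma's count stayed at 0 with TMM rescaling, edgeR, voom, both other pseudocounts, both other filters, X and Y genes left out, a threshold of 0.1 and the muscle covariate, and was 0 to 1 with 1 library left out (0 to 1 higher, 0 lower). It moved to 575 with DESeq2 (368 higher, 207 lower), 53 with library weights (35 and 18), 53 with voom and quality weights (41 and 12) and 12 with 1 surrogate variable (9 and 3). DESeq2's own count ran from 216 to 745 with 1 library left out (141 to 457 higher, 75 to 294 lower) and was 172 with the muscle covariate and without PnocCre replicate 2 (90 and 82), with fewer samples. The 21 lists became 0 with an estimated correlation, 0 with fry and 0 with the exact test (where even lists at its smallest possible p did not pass), and 17 to 22 with 1 library left out.

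The direction given by the test reversed in the following cases, and the cause was not tested. The values are log2 fold changes of genes and median log2 fold changes of lists. A list's direction comes from the mean over its members, so its median can keep its sign, or its main value, where the direction reversed. The cAMP and CREB list was at 0.035 with voom, 0.016 at a minimum mean of 100, 0.18 with 1 surrogate variable and 0.0067 in the exact test. The clock list was at 0.036 with no filter. With library weights Hspa1a was at -0.25 and the Schwann list at -0.13, and the adipokine list was at -0.12 with X and Y genes left out. With 1 surrogate variable the cold-inducible list was at -0.053, the lymphocyte list at -0.10 and the Schwann list at -0.024. With the muscle covariate Fgf21 was at 0.10, Nr4a1 at -0.056, Hspa1a at -0.58, Ckmt2 at -0.21, Des at -0.13, and the immediate early list at -0.056, creatine and calcium at -0.19, clock at -0.065, insulin and FOXO at -0.14, adipokines at -0.084, muscle at 0.055 (by construction) and Schwann at -0.24. In the exact test the mean levels of the unfolded protein and hypoxia lists pointed the other way from camera, while their medians, -0.11 and 0.023, are those of the main test. With 1 library left out Ppargc1a ran from -0.14 to 0.12, Hspa1a from -0.48 to 0.38, and the lists of cAMP and CREB from -0.13 to 0.094, clock from -0.042 to 0.094, adipokines from -0.14 to 0.012 and Schwann from -0.044 to 0.42. Near Pnoc the odds ratio was 0.535 with DESeq2 calls. At this depth low genes such as Fgf21 limit what can be told.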

Other observations

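Phgdh, the first enzyme of serine synthesis, had 290 ± 150 normalised counts against 87.5 ± 35.3, and Psat1, of the same pathway, had 186 ± 77.7 against 67.9 ± 22.4 (SD, n = 5 each, limma adjusted p 0.116 for both, DESeq2 adjusted p 3.95e-04 and 5.92e-04). The list of the unfolded protein and integrated stress response to which they belong had a median log2 fold change of -0.11 (7 of 26 higher, camera adjusted p 0.277), while fry in either direction called it (adjusted p 3.78e-04). Ryr2, a calcium release channel, had 22.9 ± 8.84 against 69.4 ± 27.4 counts, lower in PnocCre while the muscle genes of its list were higher. Igf1 had 440 ± 149 against 226 ± 42.5, and the hypoxia-responsive peptide gene Adm 42.6 ± 10.96 against 19.8 ± 8.45.

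Lists that camera did not call were cold-inducible RNA-binding and splicing (median 0.17, 13 of 14 higher, adjusted p 0.0619, with Cirbp at 0.59), pericyte and smooth muscle markers (0.21, adjusted p 0.101), erythroid markers (0.23, adjusted p 0.172), creatine and calcium cycling (0.23, adjusted p 0.241), hypoxia targets (0.02, adjusted p 0.621), Schwann cell and nerve markers (0.22, adjusted p 0.686), the circadian clock (0.04, adjusted p 0.686) and adipokines and batokines (-0.09, adjusted p 0.851). With 1 library left out camera called the cold-inducible list without PnocCre replicate 4 (0.29) or 5 (0.30) or Wildtype replicate 3 (0.19) or 4 (0.21), the pericyte list without Wildtype replicate 1 (0.36) and the erythroid list without Wildtype replicate 5 (0.50).

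Both hypotheses tested here had been written before their results, except for the test within 5 Mb. Sequence around the Cre driver is argued against as a source of many changes by the odds ratio of 1.19 for genes within 10 Mb of Pnoc, with an upper 95% limit of 1.79, but within 5 Mb the odds ratio was 1.46 with an upper limit of 2.55, so an excess close to Pnoc stays open. Libraries with neighbouring numbers may share a litter or a day. Across the groups, 4 pairs with neighbouring numbers had a mean correlation of deviations of 0.159 against -0.0300 for other pairs, with a 1-sided permutation p of 0.0998, so with 4 pairs a shared origin can neither be shown nor excluded.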
